A study of Mus musculus with 8 samples.

How the data were processed

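RNA with polyA tails was measured in LSK cells (lineage-negative, Sca1-positive, Kit-positive bone marrow cells) from 8 mice, 2 for each combination of genotype (Asxl2 knockout, KO, or wild type, WT) and age (young or old). The submitters' processing notes name kallisto, the mm10 mouse genome and DESeq2, without version numbers. The deposited tables give, for each library and each of 115088 transcripts, kallisto's estimated counts, TPM (abundance scaled for transcript length and depth) and effective length in bases. These units are those of the deposited columns, per the file headers.

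Transcripts were matched by identifier to the GENCODE vM21 annotation of the same mouse build, which paired 114200 of them with 47311 genes. The 888 unmatched transcripts held 0.259% to 0.47% of the estimated counts of a library and were left out. Of the matched transcripts, 94.2% had the same length in both sources. No mitochondrially encoded gene was among the matched transcripts, so the list of mitochondrially encoded respiratory genes was not analysed here. Estimated counts were summed per gene and rounded to whole numbers for the count models. TPM were summed per gene without rounding and are the levels given in the report, as mean ± SD.

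Library totals ran from 45737972 to 80388500 estimated counts. At that depth counting error is small next to the difference between the 2 mice of a group, which also differ in batch and litter. The chi-square per degree of freedom between the 2 replicates of a group was 86.1 in young KO, 100.1 in old KO, 85.4 in old WT and 264.6 in young WT, against 1 for counting error alone.

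Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 25543. Counts were scaled by TMM and tested by edgeR 4.0.16 quasi-likelihood F tests in R 4.3.3, and p values were adjusted by Benjamini and Hochberg over the 25543 genes, with 0.05 as the threshold. KO against WT and old against young within one age or genotype, and the genotype by age interaction, came from a model with the 4 groups and batch (3 residual degrees of freedom). The effects of genotype over both ages and of age over both genotypes came from an additive model of genotype, age and batch (4 residual degrees of freedom). Common dispersions were 0.141 and 0.134. Each group had 1 mouse in each of the 2 batches. Fold changes are log2, KO over WT or old over young, with the standard error (SE) of the fit. Other software was limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

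The labels give 4 litters, each with 1 KO and 1 WT mouse of the same age and batch. With 2 mice per group the deviations from group means mirror each other, so the check of whether littermates deviate together gives 1 value for the old and 1 for the young litters. Across genes these were 0.06 and 0.12, and -0.41 and -0.46 after removal of batch, where a model with batch forces part of the negative value. The check therefore says little on whether littermates resemble each other. Since the labels pair the mice, a model with litter as a block was run for each comparison of KO with WT. Its value is printed where it ended a call of a gene named for that comparison or moved a count by more than 1.5 times.

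The models, the alternatives, the gene lists and the rule for naming genes were written before the data were examined. The 25 lists tested covered Asxl, Bap1 and Polycomb partners, stem cell identity, lymphoid-primed progenitors, myeloid progenitors, mature neutrophils, megakaryocytes and platelets, erythroid cells, B cells, T and NK cells, macrophages with monocytes and dendritic cells, mast cells with basophils and eosinophils, marrow stroma and endothelium, hematopoietic transcription factors, Hox, Pbx and Meis genes, genes of aged stem cells, S phase, G2 and M phase, quiescence and p53 targets, interferon response, NF-kB inflammation, immediate early and stress genes, TGF-beta, Wnt and Notch signalling, adhesion and niche genes, nuclear-encoded respiratory genes and ribosomal protein genes. Shifts of a list against all other genes were tested with limma's camera on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way without comparing them with other genes, were run beside it. With the estimated correlation no list passed in any of the 7 comparisons. Fry's directional test passed for 3 lists with age over both genotypes and for S phase with age in WT mice, and for no list in the other 5 comparisons. Members that passed were also counted with p adjusted over the list alone.

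Genes named in the text follow a rule: Asxl2, Asxl1, Asxl3 and Bap1 always. For each comparison, it adds the 10 highest and 10 lowest fold changes among genes past the threshold with at least 2 TPM in the higher group, leaving out predicted gene models, Riken clones and antigen receptor segments. Up to 4 passing members of each list by lowest p are added, or 3 members of lowest p for a list that passed with no passing member. Not every such gene is printed. Genes outside the rule are said to be chosen after their values were seen.

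The alternatives tried were DESeq2, DESeq2 size factors in edgeR, no count filter, a filter of 1 CPM in 2 libraries, an offset for transcript length as in tximport, protein-coding genes only, limma-voom, limma-trend on log2 TPM with a pseudocount of 1 or 0.1 or with a filter of 1 TPM in 2 libraries, no batch term, the litter block, the 4 libraries of a contrast alone, each batch alone, and each of the 8 libraries left out. Where that left 1 mouse in a group, the spread was assumed to be like that of the other groups. Alternatives chosen only after the values were seen were a correction for transcript length (a lowess curve of log2 CPM on effective length, fitted per library with a span of 0.5 and used as an offset), the same with the litter block or with an estimated correlation, a covariate for background reads (log2 of the summed TPM of 1807 olfactory and vomeronasal receptor genes) and the data without litter 1.

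Single values per library were compared by two-sided exact permutation tests of 4 against 4 libraries. Their 70 arrangements give a smallest p of 0.0286. Adjustment was over 32 measures, 25 of them list means. These tests take the mice as independent and leave out the litters, which pair KO with WT and share an age. The tests were also tried on simulated counts of 25543 genes. For KO against WT over both ages, 57 of 100 genes changed by 2-fold and 95 of 100 changed by 4-fold were called, with 17 calls among 25343 unchanged genes. For age over both genotypes these numbers were 61, 92 and 21, and for KO against WT in old mice 25, 82 and 19. In simulated lists of 30 genes the 1 moved list was called and none of the others. The genes were simulated independently of each other, without batch, litter or length trend. These numbers therefore do not show how the tests behave for correlated genes.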

Results

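RNA was sequenced from LSK cells of 8 mice. This gate holds the blood stem cells of the marrow together with the multipotent progenitors next to them. Asxl2 encodes a partner of the chromatin enzyme Bap1 that is related to Asxl1, a gene often mutated in blood cancers, and it was knocked out in the KO mice. The 4 groups were young WT, young KO, old WT and old KO, with 2 mice each. Young mice were 8 to 12 weeks old and old mice over 1 year. Library totals were 78178864 and 45737972 estimated counts in old KO replicates 1 and 2, and 59897928 and 72105052 in young KO. In WT they were 78259996 and 56770463 in old mice and 61238010 and 80388500 in young mice. Between 26237 and 36175 genes were detected per library, and the first and second principal components held 52.9% and 17.6% of the variance.

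The first question was whether the KO libraries lacked Asxl2 RNA. Asxl2 (ENSMUSG00000037486, mm10 chromosome 12, 3426857 to 3506852) fell well below its WT level in all 4 KO libraries. It measured 26.9 ± 4.09 TPM in WT and 5.15 ± 0.431 TPM in KO libraries (SD, n = 4), a log2 change of -2.10 (SE 0.17, adjusted p = 0.000408). The change was -2.04 within batch 1 and -2.24 within batch 2. Most of the RNA left in KO libraries was assigned to the short transcript ENSMUST00000144247 of 1483 bases, at 2.946 to 4.461 TPM against 14.904 to 20.906 TPM in WT. The longest protein-coding transcript, ENSMUST00000092003 of 11934 bases, was not lower in old KO mice, at 0.376 and 0.565 TPM against 0.296 and 0.138 TPM in old WT. It was at 0.167 and 0.055 TPM in young KO and 0.269 and 0.115 TPM in young WT. Asxl1, the paralog most studied in blood, did not pass (log2 -0.23, adjusted p = 0.409), and its estimate turned to 0.18 with the length correction (adjusted p = 0.176) and to 0.14 with the background covariate (adjusted p = 0.95). Asxl3 stayed near the floor (0.145 ± 0.134 TPM in WT, 0.426 ± 0.228 TPM in KO). Its rise of 1.93 (adjusted p = 0.0439) was lost with the litter block (adjusted p = 0.0739), with the length correction (adjusted p = 0.0743) and without KO old 1 (0.115), KO old 2 (0.122), KO young 1 (0.126), WT old 1 (0.0874), WT old 2 (0.165) or WT young 1 (0.124), where the numbers are replicates.

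**Figure D1:**
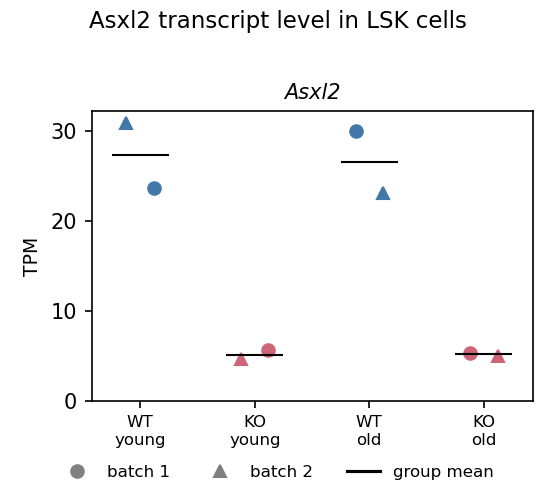
Asxl2 level in TPM (linear axis from 0) in the 8 libraries by group, circles for batch 1, triangles for batch 2, lines for group means. The 4 KO libraries averaged 5.15 TPM and the 4 WT libraries 26.9 TPM.

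The comparison of KO with WT over both ages asks which genes depend on Asxl2 in LSK cells whatever the age. Among genes that depended little on single libraries, Eya1, Mmrn1 and Pbx3 fell and Gkn3 rose. Eya1, a transcriptional coactivator with phosphatase activity (ENSMUSG00000025932, chromosome 1, 14168954 to 14310235), fell by 3.09 on the log2 scale (SE 0.19, adjusted p = 7.1e-05), from 24.1 ± 5.35 TPM in WT to 2.695 ± 0.392 TPM in KO (SD, n = 4). The extracellular matrix gene Mmrn1 (ENSMUSG00000054641, chromosome 6, 60924976 to 60989378) fell by 2.85 (SE 0.21, adjusted p = 0.000304), from 85.5 ± 53.2 to 9.61 ± 3.44 TPM. The Hox cofactor Pbx3 (ENSMUSG00000038718, chromosome 2, 34171457 to 34373142) fell by 2.66 (SE 0.21, adjusted p = 0.000304), from 11.05 ± 3.51 to 1.64 ± 0.544 TPM. Gkn3, a gastrokine gene (ENSMUSG00000030048, chromosome 6, 87383256 to 87388935), rose by 3.79 (SE 0.32, adjusted p = 0.000408), from 1.85 ± 1.58 to 23.5 ± 22.3 TPM. Within batches 1 and 2 the changes were -2.87 and -3.40 for Eya1, -2.38 and -3.41 for Mmrn1, -2.65 and -2.75 for Pbx3, and 3.25 and 4.29 for Gkn3. These 4 genes and Asxl2 passed under each of the 26 alternatives run for this comparison, as did Chn2 (log2 -1.96, adjusted p = 0.000574) and Epb41l5 (log2 -2.22, adjusted p = 0.00106), both chosen after their values were seen.

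**Figure D2:**
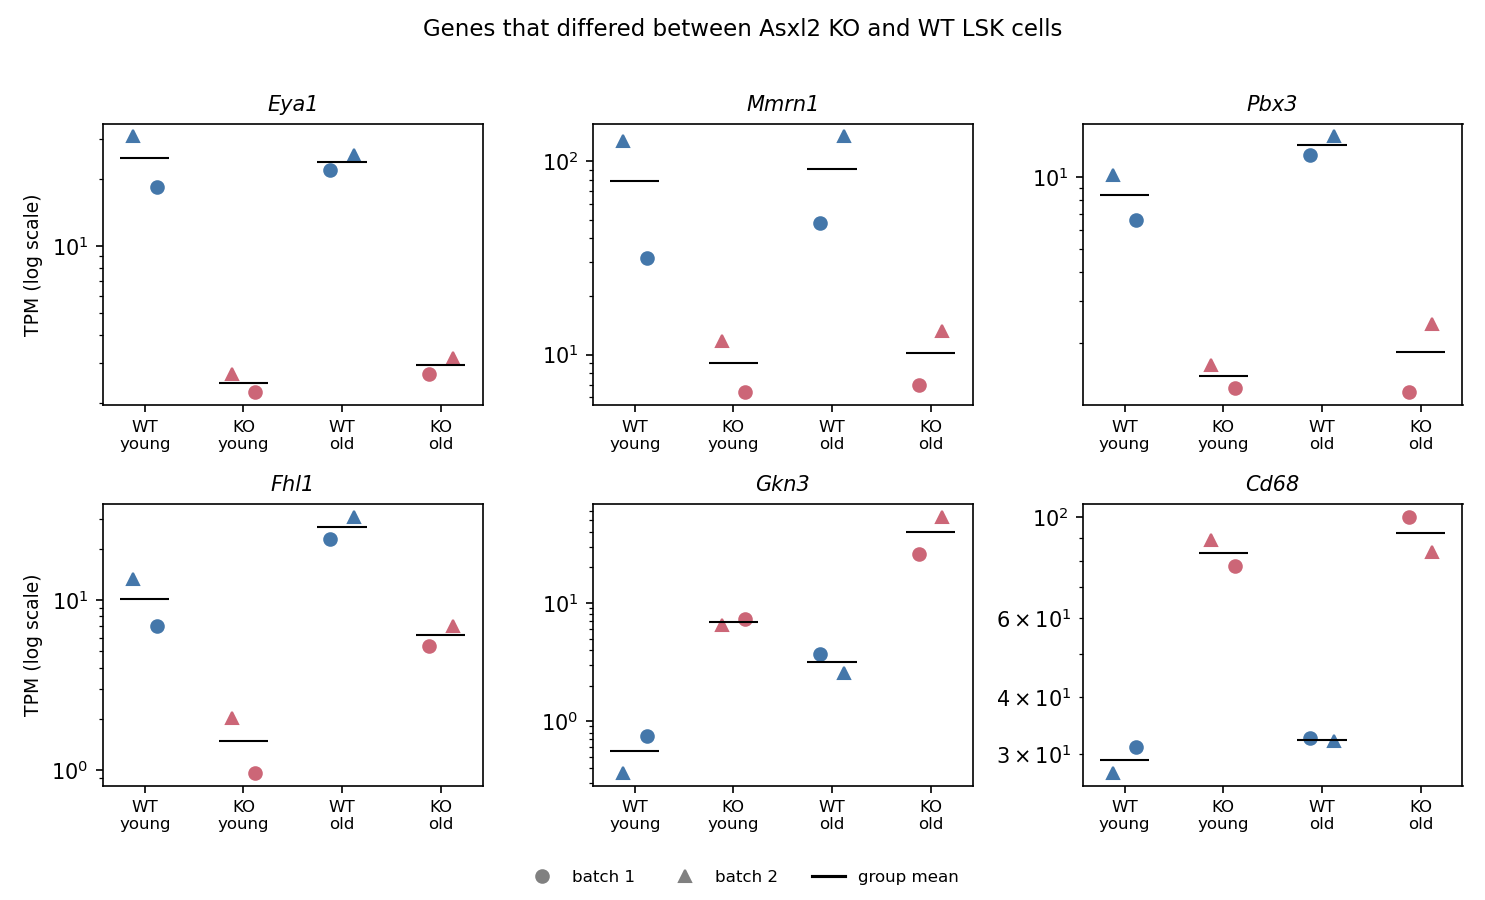
TPM on a log scale for Eya1, Mmrn1, Pbx3, Fhl1, Gkn3 and Cd68 in the 8 libraries by group, circles for batch 1, triangles for batch 2, lines for group means. In KO libraries Eya1 averaged 2.695 TPM against 24.1 TPM in WT, and Cd68 87.9 against 30.7 TPM.

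Further genes passed under 25 of the 26 alternatives and missed the threshold only with the background covariate. Cd68, which encodes a lysosomal protein of myeloid cells (ENSMUSG00000018774, chromosome 11, 69664213 to 69666153), rose by 1.67 (SE 0.16, adjusted p = 0.000663, and 0.0671 with the covariate), from 30.7 ± 2.37 to 87.9 ± 9.46 TPM. Nkg7, a granule gene of progenitors and lymphocytes, rose from 347.6 ± 47.2 to 670.1 ± 128 TPM (log2 1.08, adjusted p = 0.00626, and 0.365 with the covariate). Plek, a substrate of protein kinase C in platelets, fell from 63.5 ± 16.7 to 19.6 ± 3.74 TPM (log2 -1.53, adjusted p = 0.00151, and 0.195 with the covariate). Fhl1, a LIM-domain gene raised in aged stem cells, fell from 18.5 ± 10.6 to 3.85 ± 2.84 TPM (log2 -2.19, adjusted p = 0.00117, and 0.1 with the covariate). The adhesion gene Jam3 fell from 12.4 ± 3.45 to 3.18 ± 0.972 TPM (log2 -1.94, adjusted p = 0.00455, and 0.343 with the covariate). Of 96 named genes that passed in this comparison, 29 passed within batch 1 and 90 within batch 2.

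In all, 2548 of 25543 genes passed, 816 higher and 1732 lower in KO mice. With the litter block 1162 passed (378 higher, 784 lower), within batch 1 alone 222 and within batch 2 alone 6824. Left out 1 at a time, the libraries gave 477 without KO old replicate 1, 214 without KO old replicate 2, 751 without KO young replicate 1, 4487 without KO young replicate 2, and 590 without WT old replicate 1. They gave 138 without WT old replicate 2, 526 without WT young replicate 1 and 4787 without WT young replicate 2. The background covariate gave 9, of which 7 were among the 2548. Leaving out litter 1, the pair of mice with Xist RNA, gave 153, of which 144 were. The share of calls that were higher was 32.0%, and it was 21.8% on filtered log2 TPM and 52.0% of 1284 calls after the length correction. The median change of all genes was 0.10, against -0.16 on filtered log2 TPM, so a change near 0.2 in either direction rests on the scaling.

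The changes followed transcript length. Among 9831 protein-coding genes above 5 TPM, the shortest 10% (median effective length 492 bases) had a median log2 change of 0.42, and the longest 10% (4612 bases) one of -0.45, with a Spearman correlation of -0.63 across genes. Old against young showed 0.21 and -0.55, with a correlation of -0.65. Genes are not independent replicates, so these correlations carry no p. The trend thus adds to the changes of lists of short transcripts and takes from those of long ones, although short-transcript lists such as erythroid (median 1294 bases) and mast cell genes (811 bases) fell in KO mice. In the group paragraphs that follow, lists that gained or lost a call with the length correction are named. Per library, the slope of log2 TPM on log2 length was -0.734 ± 0.132 in KO and -0.501 ± 0.148 in WT (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.114 over 32 measures). This test leaves out the pairing by litter.

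**Figure D3:**
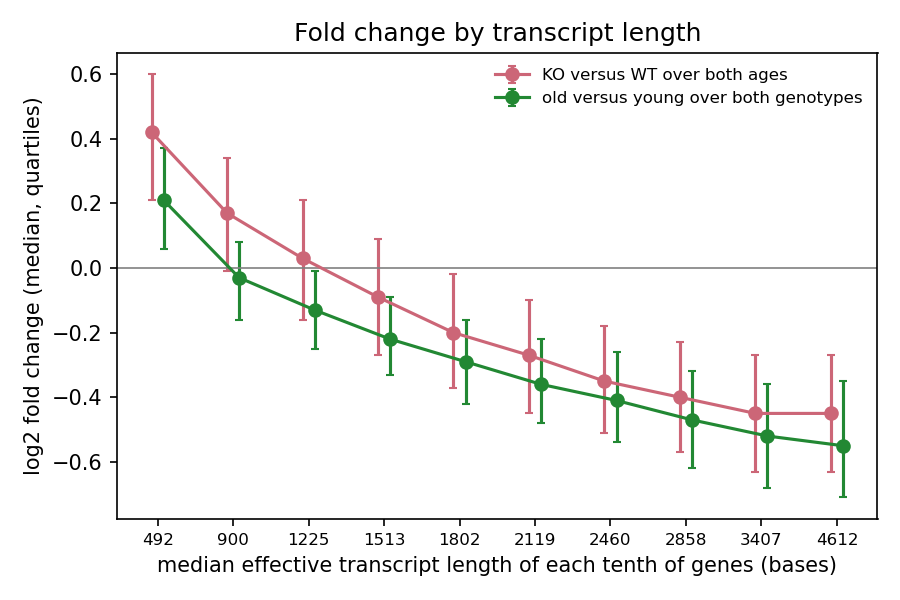
Median log2 change (y axis, bars for quartiles) of 10 groups of protein-coding genes ordered by median effective transcript length in bases (x axis, 492 to 4612), for KO against WT over both ages and old against young over both genotypes. From the shortest to the longest group the medians ran from 0.42 to -0.45 for KO and from 0.21 to -0.55 for age.

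Ribosomal protein genes and nuclear-encoded respiratory genes, which supply protein synthesis and the electron transport chain, were higher in KO libraries. Of 48 ribosomal protein genes 30 rose and 0 fell (40 rose when adjusted over the list alone). Their median log2 change was 0.63 (camera adjusted p = 6.23e-19). Rpl24 rose by 0.73, from 266.3 ± 35.5 to 394.5 ± 83.5 TPM (adjusted p = 0.0219). Of 34 respiratory genes 11 rose and 0 fell (24 and 0 adjusted over the list alone, camera adjusted p = 1.08e-09). Each list had adjusted p = 0.606 with an estimated correlation. Cox5a rose by 0.86, from 299.1 ± 27.5 to 502.9 ± 132 TPM (adjusted p = 0.0167). Both lists hold short transcripts (median 501 and 533 bases), and after the length correction 10 and 3 members rose and their medians were 0.23 and 0.14, with camera adjusted p of 0.00119 and 0.00767. The litter block gave 20 ribosomal and 5 respiratory genes. The libraries were left out in the order KO old 1, KO old 2, KO young 1, KO young 2, WT old 1, WT old 2, WT young 1, WT young 2. The ribosomal genes that rose then numbered 0, 0, 26, 25, 0, 0, 6 and 34, and the respiratory genes 0, 0, 8, 8, 1, 0, 1 and 16. Rpl24 lost its call with the length correction (log2 0.25, adjusted p = 0.0611) and without KO old 1 (adjusted p = 0.0785), KO old 2 (0.0748), WT old 1 (0.0711) and WT old 2 (0.06), and Cox5a without KO old 1 (0.05), KO old 2 (0.0643) and WT old 2 (0.0622).

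The lists of stem cell genes and of Asxl2 partners shifted down in KO libraries. The list of partners holds the knocked-out Asxl2, 1 lower gene in each of its counts below. Of 25 stem cell identity genes 3 rose and 8 fell (3 and 16 adjusted over the list alone), with a median of -0.56. Of 24 Asxl, Bap1 and Polycomb partners 1 rose and 10 fell (1 and 12 adjusted over the list alone). Each list had camera adjusted p = 5.64e-05, and adjusted p = 0.606 with an estimated correlation. Ezh1, a histone methyltransferase of quiescent stem cells, fell from 46.6 ± 15.6 to 24.2 ± 6.28 TPM (log2 -0.90, adjusted p = 0.0182). Bap1 fell from 106.7 ± 31.6 to 61.6 ± 23.5 TPM (log2 -0.67, adjusted p = 0.023), a call lost within batch 1 (log2 -0.55, adjusted p = 0.595), with the length correction (log2 -0.28, adjusted p = 0.0593) and without KO old 1 (0.077), KO old 2 (0.0995), KO young 1 (0.0913), WT old 1 (0.0733), WT old 2 (0.0772) or WT young 1 (0.0612). Both lists hold long transcripts (median 2516 and 2841 bases). After the length correction the medians were -0.22 and -0.09 and camera gave adjusted p of 0.00223 for stem cell genes (1 higher, 4 lower) and 0.0605 for the partners (2 higher, 5 lower). In the same order of libraries left out, stem cell genes that fell numbered 2, 2, 2, 11, 3, 2, 2 and 12, and partners 3, 1, 3, 12, 3, 1, 3 and 12. The litter block gave 2 and 8, and 0 of the 3 higher stem cell genes, and Ezh1 lost its call without KO old 2 (0.0854), WT old 2 (0.0704) and WT young 1 (0.0552).

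Erythroid and mast cell genes, among them genes of globins, red cell membrane proteins and granule proteases, were lower in KO libraries. Of 25 erythroid genes 1 rose and 11 fell (1 and 12 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 5.07e-05, and adjusted p = 0.606 with an estimated correlation). Carbonic anhydrase Car1 fell from 184.5 ± 43.3 to 56.7 ± 36.8 TPM (log2 -1.67, adjusted p = 0.0167). The beta globin Hbb-bs fell from 156.9 ± 98.2 to 45.5 ± 57 TPM (log2 -2.84, adjusted p = 0.031; 0.0586 with the litter block). Of 19 mast, basophil and eosinophil genes 0 rose and 7 fell (7 adjusted over the list alone; camera adjusted p = 0.0221; adjusted p = 0.778 with an estimated correlation). The mast cell proteases Tpsb2 (19.3 ± 14.8 to 1.13 ± 0.965 TPM, log2 -3.78, adjusted p = 0.0107) and Cma1 (13.45 ± 11.5 to 0.930 ± 0.365 TPM, log2 -3.28, adjusted p = 0.0162) were among them. The list's median of -0.30 turned to 0.01 and 0.05 on the log2(TPM + 1) scales. After the length correction it was -0.52 in edgeR but 0.02 on the voom values that camera uses, and both lists passed (camera adjusted p = 1.41e-06 and 0.00223). Leaving out WT old replicate 2 ended the calls of Car1 (adjusted p = 0.0784), Tpsb2 (0.0539) and Cma1 (0.0565), and Hbb-bs lost its call without KO old 1 (0.0778) or KO old 2 (0.0802). In the same order of libraries left out, erythroid genes that fell numbered 9, 3, 10, 9, 9, 1, 5 and 9 and mast cell genes 5, 5, 5, 6, 9, 0, 6 and 6. The mast cell list failed without KO young 2 (adjusted p = 0.0809), WT old 2 (0.158) and WT young 2 (0.2), and the litter block gave 6 erythroid genes.

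The lists of aged stem cell genes and of the Hox program shifted down in KO libraries as well. Both lists share members with stem cell identity, namely Mmrn1 and Slamf1, and Hoxb5 and Meis1. Of 40 genes of aged stem cells 1 rose and 12 fell (3 and 20 adjusted over the list alone; camera adjusted p = 9.58e-05, and adjusted p = 0.606 with an estimated correlation), with Mmrn1, Fhl1 and the apoptosis gene Perp (7.39 ± 1.27 to 1.85 ± 0.265 TPM, log2 -1.84, adjusted p = 0.00419) among them. With the length corrected 3 rose and 5 fell (camera adjusted p = 0.00453), and the litter block gave 4. Of 24 Hox, Pbx and Meis genes 0 rose and 4 fell (8 adjusted over the list alone; camera adjusted p = 0.0221, and adjusted p = 0.606 with an estimated correlation). Besides Pbx3 these were Hoxa9, Hoxa10 and Meis3 (6.20 ± 1.92 to 1.71 ± 0.492 TPM, log2 -1.87, adjusted p = 0.0191). The Hox list passed after the length correction (camera adjusted p = 0.00719), and Hoxa10 lost its call with the litter block (0.0795) or that correction (0.0757). Meis3 lost its call without KO old 2 (0.066), WT old 2 (0.0539) and within batch 1 (log2 -1.35, adjusted p = 0.176). In the same order of libraries left out, genes of aged stem cells that fell numbered 5, 3, 4, 13, 5, 4, 4 and 17 and Hox, Pbx and Meis genes 2, 1, 2, 7, 2, 1, 3 and 6, and without WT old 2 the Hox list failed (camera adjusted p = 0.0805).

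A further set of signalling and regulatory lists shifted down with a few passing members each. Of 30 hematopoietic transcription factors 0 rose and 5 fell (1 and 10 adjusted over the list alone; camera adjusted p = 0.000779), with Gfi1, a repressor that restrains stem cell proliferation, falling from 59.5 ± 11.5 to 28.2 ± 12.5 TPM (log2 -0.99, adjusted p = 0.0165). Of 28 adhesion and niche genes 2 rose and 7 fell (3 and 12 adjusted over the list alone; camera adjusted p = 0.00424). For 29 immediate early and stress genes 1 rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.0157), for 28 NF-kB genes 0 and 4 (1 and 9; 0.0221) and for 25 TGF-beta, Wnt and Notch genes 0 and 4 (1 and 6; 0.0221). These 5 lists had adjusted p of 0.606 to 0.611 with an estimated correlation. After the length correction all 5 failed (camera adjusted p = 0.23, 0.466, 0.126, 0.0666 and 0.466; 1, 3, 0, 1 and 1 lower genes), and the adhesion median turned from -0.29 to 0.04. The litter block gave 2, 3, 0, 2 and 1 of the lower genes. Gfi1 lost its call without KO old 2 (0.062) or WT old 2 (0.0725). The stress list failed without KO old 1 (0.0841), WT old 2 (0.158) and WT young 2 (0.0602). The NF-kB list failed without KO old 1 (0.0927), WT old 1 (0.0526) and WT old 2 (0.0805), and the TGF-beta, Wnt and Notch list without KO young 1 (0.0859) and WT old 2 (0.0508). In the same order of libraries left out, transcription factors that fell numbered 2, 0, 2, 8, 1, 0, 2 and 8, adhesion genes 1, 1, 2, 8, 2, 1, 2 and 10, and NF-kB genes 1, 0, 1, 9, 1, 0, 1 and 8. Stress genes that fell numbered 0, 0, 1, 5, 0, 0, 3 and 5 and TGF-beta, Wnt and Notch genes 0, 0, 0, 5, 0, 0, 0 and 8.

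The other 12 lists did not pass in KO against WT over both ages. For quiescence and p53 targets 2 of 25 rose and 8 fell (3 and 10 adjusted over the list alone; 1 and 5 with the litter block; 2 and 3 with the length correction; camera adjusted p = 0.062), and the list passed without KO young 2 (0.031), WT old 1 (0.0333) or WT young 1 (0.0312). Its member Cdkn1c, which keeps stem cells out of the cycle, fell from 88.8 ± 12.5 to 38.2 ± 7.72 TPM (log2 -1.03, adjusted p = 0.0167), a call lost without KO old 2 (0.0702) and within batch 1 (log2 -0.79, adjusted p = 0.345). Numbers of genes that rose and fell were 3 and 1 of 24 for myeloid progenitors (0.0979), 0 and 3 of 18 for stroma and endothelium (0.104), and 1 and 3 of 23 for megakaryocytes and platelets (0.225). They were 2 and 1 of 42 for interferon response (0.307), 3 and 0 of 30 for G2 and M phase (0.319) and 3 and 1 of 24 for lymphoid-primed progenitors (0.425). Last came 0 and 1 of 21 for T and NK cells (0.425), 2 and 0 of 30 for S phase (0.456; 1 and 0 with the litter block), 0 and 0 of 17 for mature neutrophils (0.456), 2 and 1 of 23 for macrophages (0.855) and 0 and 1 of 20 for B cells (0.914). The B cell median of 0.22 and mean of -0.26 differed in sign. With the length corrected 3 of these lists passed, each shifted up: S phase (camera adjusted p = 0.00427), G2 and M phase (0.000342) and interferon response (0.0112). With the litter block added they had 0.00564, 0.000248 and 0.00828. Myeloid progenitors passed without KO young 1 (0.00238), WT old 2 (0.0304) or WT young 2 (0.00214), and neutrophils without KO young 1 (0.0462), WT old 1 (0.0016) or WT young 1 (0.0042). Stroma passed without KO old 1 (0.0451), KO old 2 (0.0155) or WT old 2 (0.0274), interferon response without KO old 2 (0.00106) or WT old 2 (0.013), and G2 and M phase without KO old 1 (0.0127).

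KO against WT in old mice asks what loss of Asxl2 does in aged LSK cells, the age at which blood disease would be looked for. Some genes passed beside those already named. Lgals1, a galectin gene of myeloid cells, rose from 26.6 ± 0.168 to 153.8 ± 25.4 TPM (SD, n = 2; log2 2.72, adjusted p = 0.00824), and the granule protease Ctsg from 103.8 ± 22.4 to 386.1 ± 111 TPM (log2 2.06, adjusted p = 0.0192). Fos, an immediate early transcription factor, fell from 39.7 ± 0.34 to 4.55 ± 1.28 TPM (log2 -2.92, adjusted p = 0.0141). Eya1 fell by 2.96 (adjusted p = 0.00824) and passed without any single library. Mmrn1 fell by 2.89 and Pbx3 by 2.84 (both adjusted p = 0.00824). Without WT old 1 the calls of Lgals1 (0.077), Ctsg (0.107) and Fos (0.052) were lost, and without WT old 2 those of Lgals1 (0.151), Ctsg (0.158), Fos (0.158), Mmrn1 (0.151) and Pbx3 (0.125). In old mice Asxl2 itself fell by 1.88 (adjusted p = 0.0141), but missed the threshold with the litter block (0.074), without WT old 1 (0.063) and without WT old 2 (0.151).

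In old mice 166 genes passed, 52 higher and 114 lower in KO. The litter block gave 12, 5 higher and 7 lower, and the length correction gave 114 higher and 110 lower, a share of 50.9% higher against 31.3%. Leaving out KO old 2 gave 102 genes, KO young 1 1127, KO young 2 513, WT old 1 24, WT old 2 7, WT young 1 3092 and WT young 2 1958. Of 24 myeloid progenitor genes 2 rose and 1 fell (12 and 1 adjusted over the list alone; 1 and 0 with the litter block), with a median of 0.81 (camera adjusted p = 0.000115, and adjusted p = 0.622 with an estimated correlation), and this list failed without WT old 1 (0.335), the library with hardly any granulocyte RNA. Immediate early and stress genes shifted down with 1 higher and 3 lower of 29 (1 and 8 adjusted over the list alone; 0 and 1 with the litter block; camera adjusted p = 0.000119, and adjusted p = 0.622 with an estimated correlation). Ribosomal protein genes (1 and 0 of 48; 41 and 0 adjusted over the list alone; camera adjusted p = 5.43e-23; median 0.81, and 0.33 after the length correction) and respiratory genes (1 and 0 of 34; 17 and 0; 5.63e-09) shifted up. Stem cell identity (0 and 1 of 25; 2 and 13; 4.02e-06), the Asxl partners (0 and 1 of 24; 1 and 10; 0.000147), transcription factors (0 and 1 of 30; 1 and 6; 0.000235) and genes of aged stem cells (0 and 2 of 40; 1 and 5; 0.00045) shifted down. Each of these 8 lists had adjusted p = 0.622 with an estimated correlation. The 1 lower partner past the threshold over all genes was Asxl2 itself. The litter block gave 1 lower gene of aged stem cells and 1 of stem cell identity, and no single ribosomal, respiratory, partner or transcription factor gene. With single libraries left out, higher genes ranged from 0 to 30 for the ribosomal, 0 to 6 for the respiratory and 0 to 11 for the myeloid progenitor list. Lower genes ranged from 0 to 13 for stem cell identity, 0 to 11 for the partners and 0 to 10 for transcription factors and for immediate early genes. For genes of aged stem cells they ranged from 0 to 9. Another 5 lists passed but lost the call without 1 library: erythroid (0.000608; 0.0672 without WT old 2), NF-kB (0.00586; 0.0535 without KO old 1), Hox (0.0085; 0.118 without WT old 2), adhesion (0.0123; 0.117 without WT old 2) and quiescence (0.0352; 0.182 without WT old 2), with adjusted p of 0.622 to 0.666 with an estimated correlation. The litter block took the lower erythroid, quiescence and adhesion genes from 2 to 0 each. The length correction ended the calls of the partners (0.101), transcription factors (0.153), adhesion (0.734) and quiescence (0.0762). It added upward calls for S phase (0.000679), G2 and M phase (0.00377) and interferon response (0.00377).

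KO against WT in young mice asks which changes precede ageing. The genes that fell included Asxl2, Eya1, Mmrn1 and the mast cell protease Cma1. Eya1 fell from 24.6 ± 8.85 to 2.46 ± 0.333 TPM (SD, n = 2; log2 -3.22, adjusted p = 0.00385), and Cma1 from 22.6 ± 8.02 to 0.762 ± 0.432 TPM (log2 -4.80, adjusted p = 0.0079). The chemokine gene Ccl9 rose from 40.2 ± 0.353 to 106 ± 4.18 TPM (log2 1.45, adjusted p = 0.0239; 0.0904 with the litter block), a call lost without KO young 1 (0.191), KO young 2 (0.253), WT old 1 (0.131), WT old 2 (0.161) or WT young 1 (0.245). Asxl2 fell by 2.32 and Mmrn1 by 2.81 (both adjusted p = 0.0079; 0.0632 with the litter block). These 4 genes lost their calls without WT old 1 (0.0529 each) or WT old 2 (0.0656 each), Asxl2, Cma1 and Mmrn1 also without KO young 1 (0.116, 0.0924 and 0.104), and Asxl2 without KO young 2 (0.0954). In this comparison 16 genes passed, 2 higher and 14 lower. With the litter block 3 passed, 0 higher and 3 lower. Leaving out KO old 1 gave 83 genes, KO old 2 119, KO young 1 2, KO young 2 4, WT old 1 0, WT old 2 0, WT young 1 8 and WT young 2 956. In edgeR 2416 genes had an unadjusted p under 0.05 with all libraries kept, and DESeq2 called 389. Among the 12539 genes above 1 log2 CPM, the KO changes in old and in young mice, taken from separate libraries, correlated at 0.76 across genes, and at 0.72 after the length correction. Over all 25543 genes the values were 0.30 and 0.26.

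Shifts of lists in young KO mice had ribosomal protein and respiratory genes on top before the length correction, and erythroid and mast cell genes at the bottom. Ribosomal protein genes had a median of 0.40 and respiratory genes one of 0.36, with no single member past the threshold over all genes or adjusted over the list alone (camera adjusted p = 1.06e-14 and 2.57e-09). After the length correction the medians were 0.12 and 0.11. Erythroid genes had a median of -0.97 with 0 of 25 passing and 6 lower adjusted over the list alone (camera adjusted p = 3.16e-08). Genes of aged stem cells (0 and 2 of 40; 1 and 7 adjusted over the list alone; 1.28e-05) and stroma and endothelium (0 and 1 of 18; 0 and 3; 0.000725) also shifted down. Lists that passed but lost the call without 1 or more libraries were mast cells (5.54e-06; 0.109 without WT young 2), the Asxl partners (2.2e-05; 0.0549 without KO young 1), and adhesion (0.00231; 0.584 without KO young 1). The same held for stem cell identity (0.00345; 0.659 without KO young 1 and 0.378 without WT young 1), TGF-beta, Wnt and Notch (0.0047; 0.498 without KO young 1) and transcription factors (0.0213; 0.936 without KO young 1, 0.0723 without WT old 1, 0.073 without WT old 2 and 0.138 without WT young 2). With an estimated correlation all 11 lists had adjusted p of 0.674 or 0.719. The 1 lower partner past the threshold was Asxl2 itself. The length correction ended the calls of the partners (0.0589), stem cell identity (0.106), adhesion (0.371), TGF-beta, Wnt and Notch (0.299) and transcription factors (0.705). It added G2 and M phase (up, 0.000132), lymphoid-primed progenitors (up, 0.0359) and Hox genes (down, 0.0385). With the litter block added, ribosomal protein genes (0.0524), lymphoid-primed progenitors (0.0524) and Hox genes (0.0524) did not pass. The litter block alone gave no lower gene of aged stem cells, stroma, stem cell identity or the partners. With single libraries left out, lower genes ranged from 0 to 7 for aged stem cells, 0 to 5 for erythroid genes and stem cell identity, 0 to 4 for mast cells, the partners, adhesion and signalling, and 0 to 3 for stroma.

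Old against young over both genotypes asks how ageing alters LSK cells. Both mice of litter 1, which alone had Xist RNA, were old, so age is partly mixed with sex. Littermates shared age and batch, so this comparison sets 2 litters against 2, and 1 against 1 within a batch. The model takes the 8 mice as independent. Genes known to mark aged stem cells rose. Plscr2, a phospholipid scramblase gene (ENSMUSG00000032372, chromosome 9, 92275602 to 92297752), rose from 5.25 ± 1.55 TPM in young to 60.4 ± 2.52 TPM in old mice (SD, n = 4; log2 3.60, SE 0.19, adjusted p = 1.59e-05). The chloride channel regulator Clca3a1 (ENSMUSG00000056025, chromosome 3, 144729677 to 144760977) rose from 0.480 ± 0.361 to 5.17 ± 1.93 TPM (log2 3.55, SE 0.27, adjusted p = 0.000307). The chaperone clusterin, Clu, rose from 3.26 ± 1.14 to 19.7 ± 5.37 TPM (log2 2.57, SE 0.24, adjusted p = 0.00102). The stress regulator Nupr1 rose from 9.47 ± 2.89 to 68.7 ± 19.3 TPM (log2 2.44, SE 0.22, adjusted p = 0.000893), and P-selectin, Selp, from 4.74 ± 1.64 to 26.6 ± 10.1 TPM (log2 2.40, adjusted p = 0.00357; 0.134 with the background covariate). Flt3, the receptor of lymphoid-primed progenitors, fell from 327.2 ± 108 to 173.8 ± 68 TPM (adjusted p = 0.00964, and 0.895 with the covariate). Within batches 1 and 2 the changes were 3.88 and 3.31 for Plscr2, 3.74 and 3.36 for Clca3a1, 2.39 and 2.79 for Clu, 2.60 and 2.26 for Nupr1, 2.89 and 1.96 for Selp, and -1.17 and -0.82 for Flt3, and all passed. Plscr2, Clca3a1 and Clu passed under each of the 24 alternatives, as did Slc16a11 (log2 -1.93, adjusted p = 0.000893), a transporter gene chosen for this comparison after its values were seen.

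**Figure D4:**
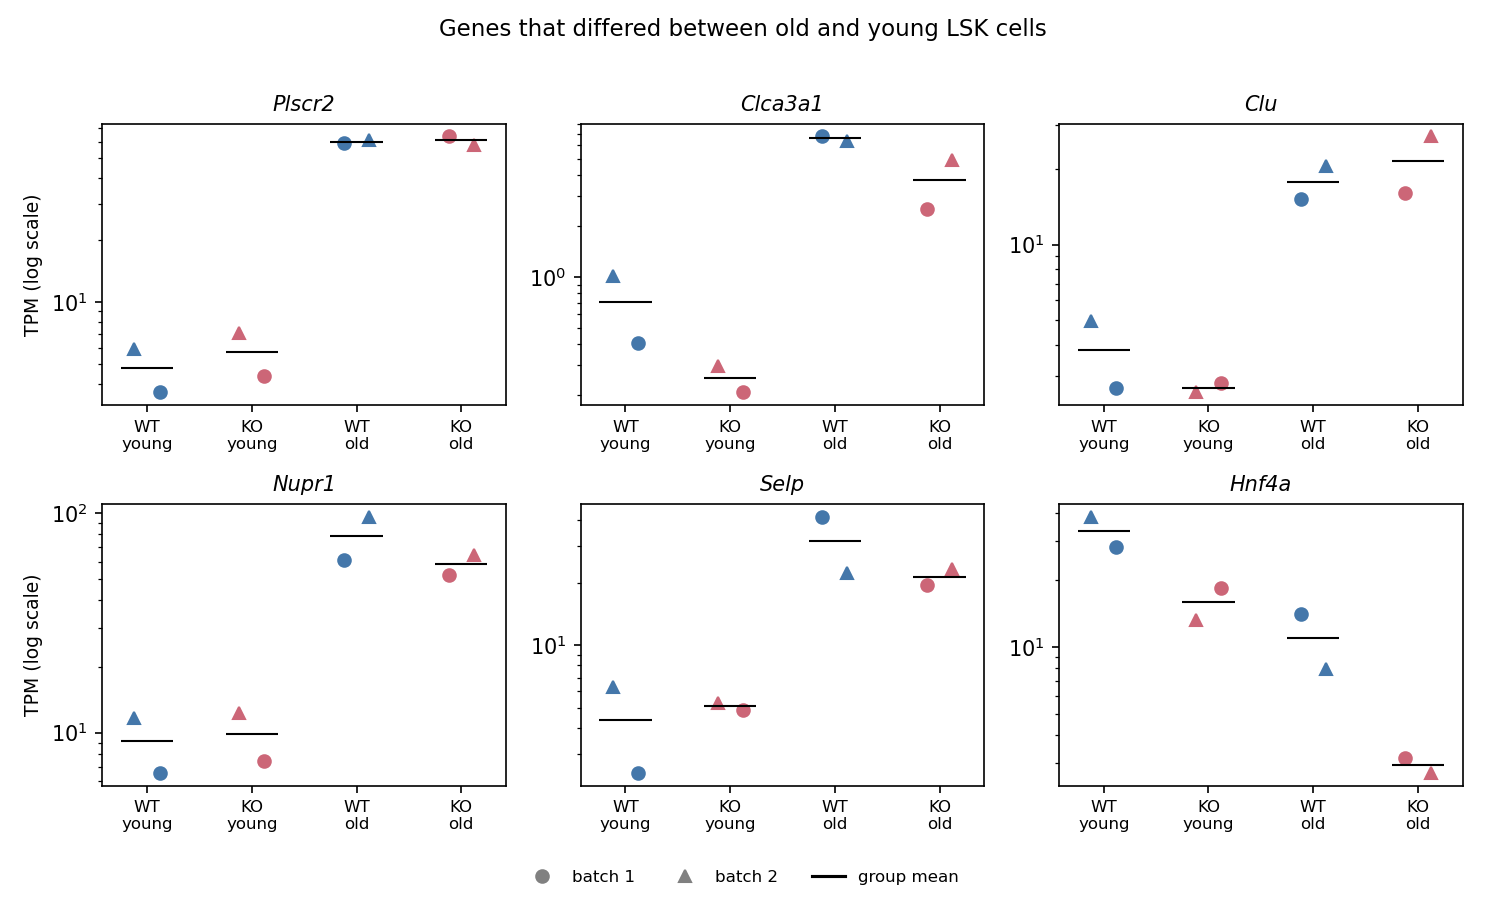
TPM on a log scale for Plscr2, Clca3a1, Clu, Nupr1, Selp and Hnf4a in the 8 libraries by group, circles for batch 1, triangles for batch 2, lines for group means. Plscr2 averaged 5.25 TPM in young and 60.4 TPM in old libraries, and Hnf4a 24.6 and 6.96 TPM.

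In all, 3563 genes passed with age, 1109 higher and 2454 lower in old mice, and 2731 passed within batch 1 and 1879 within batch 2. Leaving out KO old 1 gave 115 genes, KO old 2 159, KO young 2 44, WT old 1 393 and WT young 1 83. The length correction gave 206, of which 167 were among the 3563 and 72.8% were higher, against 31.1% before. For the 998 higher genes whose call ended, the median change grew from 1.67 to 1.93 (median SE 0.45 to 0.50), and for the 2398 lower ones it shrank from -0.64 to -0.22 (SE 0.15 to 0.09). On log2(TPM + 1), log2(TPM + 0.1) and filtered log2(TPM + 1) 42, 60 and 68 genes passed, with 85.7%, 81.7% and 77.9% higher. The background covariate gave 16 genes, 14 of them among the 3563, and leaving out litter 1 gave 20, 16 of them so. The median change of all genes was 0.15, and 0.26 after the length correction. Of 94 named genes that passed, 57 passed within batch 1, 67 within batch 2 and 49 within both.

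Genes of aged stem cells and of platelets rose with age while S phase genes fell. The lists of aged stem cells and of platelets share Selp, Vwf, Itgb3 and Cavin2, so their shifts are not independent. Of 40 genes of aged stem cells 20 rose and 2 fell (23 and 4 adjusted over the list alone), with a median of 1.12 (camera adjusted p = 4.61e-09, and adjusted p = 0.455 with an estimated correlation). With the length corrected 21 rose and 0 fell. Of 30 S phase genes 0 rose and 16 fell (0 and 22 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 1.93e-12; adjusted p = 0.0961 with an estimated correlation). The replication helicase gene Mcm2 fell from 233.1 ± 43 to 146.3 ± 34.9 TPM (log2 -0.72, adjusted p = 0.0173), a call lost without KO old 1 (0.0594), KO young 2 (0.0967) and WT young 1 (0.0688). After the length correction no S phase gene passed and the median was -0.15 (camera adjusted p = 1.05e-08). For megakaryocytes and platelets 5 rose and 1 fell of 23 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0221, and adjusted p = 0.455 with an estimated correlation), and the list failed without WT old 2 (0.0967) or WT young 2 (0.0768). Cavin2, a caveolar gene of platelets, rose from 3.79 ± 1.51 to 16.3 ± 5.95 TPM (log2 2.09, adjusted p = 0.00155). In the order of libraries left out used above, genes of aged stem cells that rose numbered 15, 16, 20, 10, 17, 20, 17 and 20, platelet genes 3, 3, 6, 2, 5, 5, 5 and 5, and S phase genes that fell 0, 3, 11, 0, 6, 15, 0 and 17.

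Lists of long transcripts also fell with age. The Asxl, Bap1 and Polycomb partners had 0 higher and 11 lower of 24 (0 and 13 adjusted over the list alone; camera adjusted p = 4.19e-06), and adhesion and niche genes 1 and 10 of 28 (2 and 15; 3.12e-05). Higher and lower members were 0 and 5 of 30 transcription factors (0 and 8; 3.12e-05) and 0 and 7 of 25 TGF-beta, Wnt and Notch genes (1 and 11; 0.00241). With an estimated correlation each of these 4 had adjusted p = 0.455. After the length correction their medians were -0.08, -0.06, 0.06 and -0.05. The partners (camera adjusted p = 0.00392), adhesion (0.0118) and TGF-beta, Wnt and Notch genes (0.0258) still passed, and transcription factors did not (0.114). None of the lower members of these 4 lists passed any more, nor did any G2 and M phase gene. G2 and M phase genes had 0 and 4 of 30 (0 and 4 adjusted over the list alone; camera adjusted p = 1.62e-05; adjusted p = 0.271 with an estimated correlation) and a median of 0.02 after the length correction (camera adjusted p = 0.0622). Bap1 fell from 104.3 ± 34 to 64.0 ± 25.7 TPM (log2 -0.79, adjusted p = 0.0198; 0.0652 with the length correction), a call lost without KO old 1 (0.0637), KO old 2 (0.0748), KO young 2 (0.0967) and WT young 1 (0.0716). In the order used above, partners that fell numbered 0, 1, 6, 0, 2, 10, 0 and 13, and adhesion genes 0, 0, 6, 0, 1, 12, 1 and 10. Transcription factors numbered 0, 0, 3, 0, 1, 7, 0 and 7, signalling genes 0, 0, 3, 0, 0, 7, 0 and 10, and G2 and M phase genes 0, 0, 1, 0, 0, 0, 0 and 5.

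Genes of maturing cells moved with age too. Of 25 erythroid genes 0 rose and 7 fell (0 and 8 adjusted over the list alone; camera adjusted p = 0.00118, and adjusted p = 0.455 with an estimated correlation), with the globin Hbb-bt falling from 111.6 ± 17.3 to 44.4 ± 12.7 TPM (log2 -1.32, adjusted p = 0.0207). With the length correction 1 erythroid gene was lower and no mature neutrophil gene passed, while both lists did (3.78e-05 and 1.69e-06). Of 17 mature neutrophil genes 0 rose and 2 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.000972; adjusted p = 0.54 with an estimated correlation), and WT old replicate 1 held hardly any RNA of such genes. Ribosomal protein genes had 4 higher and 0 lower of 48 (0 adjusted over the list alone; camera adjusted p = 2.79e-05; adjusted p = 0.727 with an estimated correlation), and neither this shift nor any member passed after the length correction (adjusted p = 0.4). Stem cell identity genes had 1 higher and 4 lower of 25 (3 and 11 adjusted over the list alone; camera adjusted p = 0.0481; adjusted p = 0.834 with an estimated correlation), a call lost without KO old 2 (0.248), KO young 2 (0.254), WT old 1 (0.139) and WT young 1 (0.0883). Their median of -0.28 turned to 0.02 after the length correction (camera adjusted p = 0.465; 1 higher, 0 lower) and to 0.20 with the background covariate. Hbb-bt lost its call without KO old 2 (0.0504), KO young 2 (0.102) and WT young 1 (0.0666). In the order used above, erythroid genes that fell numbered 3, 4, 6, 0, 4, 11, 1 and 6, and ribosomal genes that rose 0, 0, 3, 0, 1, 2, 0 and 6.

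Within WT mice alone, old against young asks for the ageing of normal LSK cells. Fos rose from 1.83 ± 0.478 to 39.7 ± 0.34 TPM (SD, n = 2; log2 4.52, adjusted p = 0.00285) and Plscr2 from 4.75 ± 1.58 to 60.07 ± 1.5 TPM (log2 3.61, adjusted p = 0.00149), and both passed without any single library. Aldh1a1, an aldehyde dehydrogenase of aged stem cells, rose from 8.71 ± 4.13 to 64.2 ± 8.05 TPM (log2 2.85, adjusted p = 0.00961), a call lost with the length correction (0.0538) and without WT old 1 (0.13) or WT old 2 (0.109). In all 22 genes passed, 17 higher and 5 lower, and 3543 had an unadjusted p under 0.05. Leaving out KO old 1 gave 82, KO old 2 98, KO young 1 34, WT old 1 7 and WT young 2 1107. Genes of aged stem cells had 7 higher and 0 lower of 40 (19 and 2 adjusted over the list alone; camera adjusted p = 9.26e-16; adjusted p = 0.619 with an estimated correlation), while no S phase gene passed over all genes. Adjusted over the list alone, 18 of 30 S phase genes were lower (camera adjusted p = 1.18e-16; adjusted p = 0.307 with an estimated correlation). With single libraries left out, 2 to 13 genes of aged stem cells were higher and 0 to 6 S phase genes lower. Megakaryocyte and platelet genes shifted up (2 and 0 of 23; 3 and 0 adjusted over the list alone; camera adjusted p = 0.000176), and the Asxl partners (4.57e-06), adhesion (9.3e-06), erythroid (1.59e-05) and TGF-beta, Wnt and Notch genes (0.000195) down, with adjusted p = 0.619 each with an estimated correlation. Another 5 lists fell but lost the call without 1 library or more: G2 and M phase (9.3e-06; 0.126 without WT old 2), myeloid progenitors (6.39e-05; 0.572 without WT old 1, 0.453 without WT young 2), and mast cells (0.000405; 0.493 and 0.573 without the same). So did mature neutrophils (0.000686; 0.903 and 0.298 without the same) and transcription factors (0.00111; 0.445 without WT old 1). The length correction ended the call of transcription factors (0.324) and added immediate early and stress genes (up, 0.00285), Hox genes (up, 0.0235) and respiratory genes (down, 0.0235). The 2 higher platelet genes, Selp and Cavin2, are also on the list of aged stem cells.

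Within KO mice, old against young asks whether cells without Asxl2 age alike. Clca3a1 (log2 3.86, adjusted p = 0.00345), Plscr2 (log2 3.60, adjusted p = 0.00154) and the interferon-linked gene Phf11d (5.98 ± 1.4 to 47.5 ± 1.16 TPM, SD, n = 2, adjusted p = 0.00345) rose. Hnf4a, a nuclear receptor gene, fell from 15.9 ± 3.71 to 2.93 ± 0.309 TPM (log2 -2.52, adjusted p = 0.00345). Each of these calls was lost without KO young replicate 2 (adjusted p = 0.0835, 0.0604, 0.122 and 0.0835). In all 22 genes passed, 16 higher and 6 lower, and 6224 had an unadjusted p under 0.05. Leaving out KO old 1 gave 53, KO old 2 126, KO young 1 1006, KO young 2 0, WT old 2 13, WT young 1 2772 and WT young 2 1486. Genes of aged stem cells had 7 higher and 0 lower of 40 (21 and 2 adjusted over the list alone; camera adjusted p = 3.55e-08, and adjusted p = 0.695 with an estimated correlation). No S phase gene passed over all genes, and 15 were lower adjusted over the list alone (camera adjusted p = 2.74e-08, and adjusted p = 0.695 with an estimated correlation). In the data with 1 library fewer, 0 to 20 genes of aged stem cells and 0 to 7 ribosomal genes were higher, and 0 to 11 S phase genes and 0 to 10 partners lower. Ribosomal protein genes shifted up with 25 of 48 higher adjusted over the list alone (2.29e-09; median 0.57, and 0.22 after the length correction), and transcription factors (1.65e-05), the Asxl partners (2.85e-05; 9 lower adjusted over the list alone) and adhesion genes (0.000384; 2 and 11) down. Another 6 lists lost their calls without 1 library or more, and all 12 had adjusted p = 0.695 with an estimated correlation. The length correction ended the calls of transcription factors (0.0821) and adhesion genes (0.0821) and of 4 of those 6 lists: stem cell identity (0.0871), G2 and M phase (0.211), quiescence (0.119) and TGF-beta, Wnt and Notch (0.177). It added megakaryocytes and platelets (0.0209) and interferon response (0.0237), both up.

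The interaction asks whether the effect of Asxl2 loss differs between ages, and for hardly any gene could a difference be shown. The 1 gene that passed was the antibody segment Ighv7-1 (adjusted p = 0.0068), with 185 counts in KO old replicate 1, 2307 in WT young replicate 2, 1 in WT old replicate 1 and 0 in the other 5 libraries. In edgeR 505 genes had an unadjusted p under 0.05, DESeq2 called 10 and limma-voom 0. Leaving out KO old 1 gave 11, KO old 2 15, KO young 1 2, KO young 2 0, WT old 1 0, WT old 2 5 and WT young 2 11. Fos, at 39.7 ± 0.34 TPM in old WT and 4.55 ± 1.28 TPM in old KO but 1.83 ± 0.478 and 2.48 ± 0.628 TPM in young WT and KO (SD, n = 2), had an interaction of -3.74 that did not pass (adjusted p = 0.222). Of the lists, 9 passed with no member past the threshold. Myeloid progenitor genes shifted up (median 0.78, 4 higher adjusted over the list alone; camera adjusted p = 8.29e-13) and immediate early and stress genes down (3 lower adjusted over the list alone; 9.08e-08), both with adjusted p = 0.692 with an estimated correlation. The other 7 lost their calls without 1 or more libraries, among them ribosomal protein genes (5.33e-16; 0.515 without WT old 1) and mast cell genes (1.59e-05; 0.216 without WT old 1 and 0.242 without WT young 2), each with adjusted p = 0.692 with an estimated correlation. The length correction ended the calls of transcription factors (0.357) and respiratory genes (0.25) and added S phase (0.00101) and interferon response (0.0202), both up.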

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

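The tests on WT old replicate 1 in this part were chosen only after its values were seen. Each value per library was compared with the other 3 libraries of its genotype, and a value was singled out when its gap to the nearest other, as a share of the range, exceeded Dixon's critical value. Chance singles out about 1 in 20 groups of 4, so 7.1 of the 142 checks would be expected, and 12 were found. Each group of 4 held 2 young and 2 old mice.

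WT old replicate 1 held little RNA of granulocytes. Its mean log2(TPM + 1) was 1.26 over the mature neutrophil list, against 4.48 to 4.8 in the other WT libraries, and 1.69 over the mast cell, basophil and eosinophil list, against 4.05 to 4.48. The eosinophil granule gene Prg2 was at 1.0 TPM there and at 488.5 to 1693.3 TPM in the other 7 libraries, and the neutrophil gene S100a9 was at 1.9 TPM against 12.1 to 304.4 TPM. Its quiescence and p53 list was higher, at 4.84 against 4.68 to 4.7.

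A lower share of granulocytes, or of their RNA, in that sort stays open. WT old replicate 1 was the lowest of the 8 libraries for 20 of the 30 members of both granulocyte lists above 2 TPM on average, which restates the low means and supports no explanation. All 30 were thus detected in cells sorted as LSK, although a gate without lineage markers should remove mature granulocytes, and Il1b is also on the NF-kB list. The sex of litter 1, whose mice alone carried Xist RNA, is argued against, since the littermate KO old replicate 1 had Prg2 at 488.5 TPM. No other biological explanation was tested, and genotype and age cannot set 1 of 2 old WT mice apart from the other.

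KO old replicate 1 was low for the lymphoid-primed progenitor list, at 4.5 against 4.78 to 4.83 in the other KO libraries, and for G2 and M phase, at 5.99 against 6.49 to 6.58. WT young replicate 1 was high for adhesion and niche genes, at 6.14 against 5.8 to 5.83. Its slope of log2 TPM on log2 length was -0.279, against -0.589 to -0.565 in the other WT libraries.

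Among named genes, Sprr2a2 was at 0.917 TPM in WT old replicate 2 against 0.0283 to 0.0729 TPM in the other WT libraries, and at 6.1 TPM in KO old replicate 1 against 0.714 to 0.977 TPM. The red cell genes Slc4a1 and Alas2 were at 1.38 and 3.18 TPM in KO young replicate 1, against 0.0506 to 0.258 and 0.309 to 0.744 TPM in the other KO libraries. Upk3bl was at 5.14 TPM in WT old replicate 1 against 0.105 to 0.924 TPM.

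The KO effect on the antibody segment Ighv7-1 differed between old and young mice by the interaction test (adjusted p = 0.0068). With nearly all its counts in WT young replicate 2 (2307) and KO old replicate 1 (185), the test rests on single animals.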

How the results depend on the processing

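The length corrections, the background covariate and the data without litter 1 were chosen after the values were seen. Numbers are genes past the threshold. The main counts were 166 for KO in old mice, 16 for KO in young mice, 22 for age in WT, 22 for age in KO, 1 for the interaction, 2548 for KO over both ages and 3563 for age over both genotypes. The cause of the differences was not tested, except that some fits used fewer genes or mice by construction.

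Some gene results held under the alternatives run. Asxl2 fell under every alternative run for KO over both ages, by 1.97 to 2.21 on the log2 scale when single libraries were left out. Of the 2548 genes, 53 passed under all 22 alternatives fixed in advance (7 higher, 46 lower), and of the 3563 genes with age 16 under all 21 (13 higher, 3 lower). In KO in old mice, KO in young mice, age in KO and the interaction 0 genes in edgeR did so, and in age in WT 1 did. Asxl1, which did not pass, was the gene whose direction reversed: it was 0.18 with the length correction, 0.18 with that and the litter block and 0.14 with the background covariate.

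DESeq2 called 3344 for KO in old mice, 389 for KO in young mice, 393 for age in WT, 3548 for age in KO, 10 for the interaction, 5381 for KO over both ages and 6735 for age over both genotypes. Without a count filter these were 2517, 421, 1015, 2943, 75, 4237 and 6489. With 1 CPM in 2 libraries they were 587 for KO in old mice, 8 for KO in young mice, 10 for age in WT, 0 for the interaction and 2140 for age over both genotypes. Protein-coding genes alone gave 1348 for KO in old mice, 14 for age in WT, 0 for the interaction and 2198 for age over both genotypes. The transcript length offset gave 106 for KO in old mice. Limma-voom gave 1554 for KO in old mice, 1336 for age in KO, 0 for the interaction and 5624 for age over both genotypes.

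On log2(TPM + 1) the counts were 1553 for KO in old mice, 0 for KO in young mice, 2 for age in WT, 4 for age in KO, 0 for the interaction and 42 for age over both genotypes. With a pseudocount of 0.1 they were 1242, 0, 2, 4, 0 and 60, and with a filter of 1 TPM in 2 libraries 1814, 0, 3, 6, 0 and 68. These scales moved the median change of all genes from 0.07 to -0.24 in old KO mice and from 0.10 to -0.16 in KO over both ages (filtered). The share of calls that were higher went from 31.3% to 20.1% and from 32.0% to 21.8%. The mast cell list's median for KO over both ages turned from -0.30 to 0.05 there.

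Without a batch term the counts were 0 for KO in old mice, 0 for KO in young mice, 2 for age in WT, 6 for age in KO, 0 for the interaction, 374 for KO over both ages and 168 for age over both genotypes. In the main edgeR models the first 2 and the interaction had 5405, 2416 and 505 genes at an unadjusted p under 0.05. With the litter block they were 12 for KO in old mice, 3 for KO in young mice and 1162 for KO over both ages. Passing list members also moved by more than 1.5 times with the block. Over both ages, higher members went from 1 to 0 for the partners and for genes of aged stem cells and from 2 to 1 for interferon response and adhesion. In old mice the megakaryocyte (1 higher, 1 lower), macrophage (1 higher) and stroma (1 lower) lists went to 0, and in young mice the Hox list (1 lower) did. The block alone changed no list call. With the length correction as well, the mast cell list passed in old mice (down, camera adjusted p = 0.0226), against 0.101 with the length correction alone. Fits of only the 4 libraries compared gave 1665 for KO in old mice, 7 for KO in young mice, 494 for age in WT and 4761 for age in KO. Within batch 1 KO over both ages gave 222, within batch 2 it gave 6824, and age within batch 2 gave 1879.

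Leaving out single libraries gave 7 to 3092 for KO in old mice, 0 to 956 for KO in young mice, 7 to 1107 for age in WT, 0 to 2772 for age in KO, 0 to 15 for the interaction, 138 to 4787 for KO over both ages and 44 to 4935 for age over both genotypes. Counts of genes near the threshold in these data therefore rest on single mice, while the named genes that passed without any single library do not. Without litter 1 the counts were 4, 2, 4, 4, 2, 153 and 20, from 6 mice in place of 8.

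The length correction gave 8 for age in WT, 0 for the interaction, 1284 for KO over both ages and 206 for age over both genotypes. Together with the litter block it gave 28 for KO in old mice, 1 for KO in young mice, 0 for the interaction and 610 for KO over both ages. It raised the median change of all genes with age over both genotypes from 0.15 to 0.26, in WT from 0.06 to 0.21 and in KO from 0.18 to 0.29. In simulated counts that held the length trend alone, the uncorrected models called 60 and 12 of 25543 genes for KO and age, and the corrected models 4 and 3. The simulation took the spread of each gene from the uncorrected data, which already holds trend differences within groups. Its counts can therefore understate the calls that the trend makes. The background covariate gave 9 for KO over both ages and 16 for age over both genotypes, in a fit with 1 residual degree of freedom fewer.

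Lists that passed numbered 13, 11, 12, 12, 9, 13 and 12 in the order of the first paragraph. With an estimated correlation 0 passed in camera in each of the 7 comparisons, also after the length correction. Permutation tests of the list means called none for KO or age (lowest adjusted p = 0.114 and 0.305), with 0.0286 the smallest p possible. For KO in young mice 6 passed with the length correction and the litter block. With single libraries left out they numbered 12 to 17, 9 to 16, 12 to 16, 11 to 16, 6 to 16, 11 to 15 and 11 to 15.

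Depth limited genes of few counts only. Genes near the floor such as Asxl3 rest on few reads, and their values cover counting error and the spread of few mice at once.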

Other observations

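The tests of the length pattern and of other groupings of the mice were chosen after their results were seen. Those of the link between the KO and age changes were written before theirs.

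The class II antigen presentation genes H2-Eb1 and H2-Aa were higher in old mice. H2-Eb1 went from 73.9 ± 45.7 TPM in young to 283.4 ± 131 TPM in old mice (SD, n = 4, log2 2.06, adjusted p = 0.0219). H2-Aa went from 126.1 ± 60.9 to 365.4 ± 180 TPM (log2 1.63, adjusted p = 0.0287). Both calls were lost without KO old 1 (adjusted p = 0.0694 and 0.0981), KO young 2 (0.117 and 0.135), WT old 2 (0.054 and 0.0901) or WT young 1 (0.0743 and 0.0834), and with the length correction (log2 2.05 and 1.59, adjusted p = 0.0607 and 0.0728). The B cell list that holds them had 5 higher and 0 lower of 20 members and did not pass (7 and 1 adjusted over the list alone, 0 and 0 over all genes with the length correction, camera adjusted p = 0.178), although it passed without KO old 2 (0.00272), KO young 1 (0.0199) or WT old 1 (0.0143). The light chain gene Igkc varied from 0.0 TPM in KO young replicate 2 to 4207.4 TPM in WT old replicate 2. The T cell gene Cd3e stayed at or under 0.3 TPM and the macrophage gene Adgre1 at or under 0.9 TPM in each library.

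The remaining lists did not pass with age over both genotypes. Members that rose and fell were 1 and 5 of 24 for lymphoid-primed progenitors (camera adjusted p = 0.11), 1 and 0 of 19 for mast cells (0.125), and 2 and 5 of 25 for quiescence and p53 targets (0.0657). Further lists had 5 and 6 of 28 for NF-kB genes (0.415) and 4 and 2 of 24 for Hox, Pbx and Meis genes (0.42). Quiescence passed without WT old 2 (0.0295). Lymphoid-primed progenitors passed without KO old 2 (0.0265) or WT young 1 (0.0264). The mast cell list passed without KO old 1 (0.0353), KO old 2 (0.0248), KO young 1 (0.00676), WT old 2 (0.0295) or WT young 1 (0.0233), and after the length correction (down, 0.00554). Members that rose and fell were also 3 and 2 of 21 for T and NK cells (0.42), 1 and 2 of 24 for myeloid progenitors (0.429), and 0 and 1 of 34 for respiratory genes (0.444). Last were 2 and 1 of 29 for immediate early genes (0.853), 0 and 2 of 42 for interferon response (0.868), and 0 and 2 of 23 for macrophages and 2 and 0 of 18 for stroma (both 0.928). Interferon response passed without KO old 2 (0.0251) and respiratory genes without WT old 1 (0.0388). With the length correction no NF-kB gene and no Hox, Pbx or Meis gene passed, and 1 higher and 1 lower lymphoid-primed and 1 higher and 0 lower quiescence genes did. The NF-kB median of -0.07 and mean of 0.27, and the immediate early median of -0.08 and mean of 0.26, differed in sign.

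Kit, the receptor used in the sort and chosen here after its values were seen, fell from 261.3 ± 194 TPM in WT to 113.9 ± 46.1 TPM in KO mice (SD, n = 4, log2 -0.88, adjusted p = 0.0438) and with age from 246.3 ± 201 to 128.9 ± 69.2 TPM (log2 -0.93, adjusted p = 0.0324). WT young replicate 1, at 547.2 TPM, lies in the higher group of both comparisons, the other 7 libraries held 63.4 to 218.6 TPM, and the alternatives were not tabulated for Kit. Ly6a, which encodes the sort marker Sca1, rose from 221.7 ± 52.8 to 396.5 ± 180 TPM in KO mice (log2 0.90, adjusted p = 0.0321, 0.0574 with the litter block, 0.0552 with the length correction). That call was lost without KO old 1 (0.0963), KO old 2 (0.0618), WT old 1 (0.0669), WT old 2 (0.0626) or WT young 1 (0.0683). RNA of olfactory and vomeronasal receptors, which LSK cells are not known to use, summed to 557.6 and 408.6 TPM in old KO, 162.2 and 135.6 in young KO, 280.6 and 91.6 in old WT and 40.5 and 160.8 in young WT (replicates 1 and 2; KO against WT, n = 4, exact permutation p = 0.2).

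KO changes over both ages fell with transcript length, at a Spearman correlation of -0.63 across genes with the litter block. The trend as the whole cause of the calls is argued against, since 419 of 1162 genes called with the litter block (36.1%; 134 higher, 285 lower) were called again in the same direction with the length offset. For the 499 lower genes whose call ended, the median change went from -0.76 to -0.38 (median SE 0.16 to 0.10), and for the 244 higher ones from 0.86 to 0.50 (SE 0.19 to 0.16), so those calls ended because the change shrank. Background reads in proportion to transcript length would not make changes fall with length, so they are argued against by the same -0.63. Background reads of other kinds cannot be told apart from an effect of genotype. The receptor RNA went with the slope of log2 TPM on log2 length across the 8 libraries (Pearson r = -0.91, permutation p = 0.00342, Spearman -0.69, permutation p = 0.0694; r = -0.62 without the 2 libraries farthest from the median), the slope differed along genotype, and the background covariate gave 9 genes, 7 of them among the 2548. A difference in RNA quality or yield between KO and WT libraries cannot be told apart from an effect of genotype: the slope on length was lower in the KO library in 4 of 4 litters, as both would give, and no measure of RNA quality was analysed here. An effect of Asxl2 loss on long transcripts stays open, untested.

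Of 1732 genes lower in KO mice, 976 were also lower in old mice, against 166.4 for independent lists, and 21 were higher. Both comparisons use the same 8 libraries. The list of aged stem cell genes went apart, with 1 higher and 12 lower in KO mice but 20 higher and 2 lower in old mice. Across 12539 genes above 1 log2 CPM, the changes correlated at 0.59, and at 0.49 after the length correction, which argues against the length trend as the cause. The link was also present between changes that share no library. The KO change of batch 1 and the age change of batch 2 correlated at 0.46, and the converse pair at 0.45. After the length correction these were 0.32 and 0.41. Chance states of single libraries are not excluded by this. The first principal component held 52.9% of the variance, so unrelated contrasts can correlate too, in either direction. What stays open is a shared effect of Asxl2 loss and age, on LSK cells or on the mix of cells sorted. RNA quality, which could differ along both, and chance states of single libraries stay open too. The shared effect is a hypothesis from the same data.

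Other groupings of the 8 mice into 4 and 4 gave few genes. For KO against WT, 1 of 33 splits, the real one, gave as many as 2548 genes, and the highest other gave 3. The litters pair the mice, and the 8 splits that part all 4 litters, of which the highest other gave 1, are too few for a share under 5%. The other splits also leave the difference between KO and WT in the residual, which lowers their counts. For age, 1 of 33 splits gave as many as 3563, and the highest other gave 10. Only 2 of these splits keep all litters together, too few for such a share as well, and the other of them gave 0 genes in edgeR.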
